A study of Mus musculus with 12 samples.

How the data were processed

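Poly(A) RNA of mouse cholangiocyte lines KPCh and iAKP was sequenced from 12 libraries, 3 per group, after culture with or without 100 nM RMC-7977 for 24 h. The groups were KPCh untreated, KPCh treated, iAKP untreated and iAKP treated, and each library's group was taken from its labels. Both lines are labelled as mutant for KRAS and TP53 and as coming from liver. The labels describe a strand-specific dUTP library preparation, sequencing on a NextSeq2000 and growth in DMEM with serum. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. KPCh carries the batch label R1 and iAKP the batch label R2, so line and batch cannot be told apart in any comparison of the lines.

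The deposited values were raw counts of read pairs per gene, one table per library. The counts were made by the authors with featureCounts 1.6.0 on the GENCODE vM34 annotation, per the file headers, with neither multimapping reads nor reads overlapping several genes counted. Per the file headers, the authors counted the KPCh libraries without strand (option 0) and the iAKP libraries as reverse-stranded (option 2). In KPCh, reads overlapping exons of genes on both strands therefore could not be assigned by strand and were left out as overlapping several genes. Of the 16587 tested genes, 11334 (68.3%) had no exon overlapped by one on the opposite strand. Among the genes named, the share of exon length overlapped was 0.381 for Notum, 0.29 for Tapbp, 0.262 for Slc13a2, 0.244 for Spry1 and 0.228 for Ube2c. It was lower but above 0 for others, from 0.139 for Fgfr3, 0.128 for Hexa and 0.12 for Csf2 down to 0.016 for Tk1 and 0.0017 for Erbb2, and the KPCh counts of all such genes are uncertain to that extent. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.9a, genome build GRCm39, edgeR and limma were used, the last pair without a version and with no step named. Reads from near-identical paralogs were lost where they mapped to several places, so members of gene families such as Prl2c2, Saa3, Ifit3 and the H2 genes are uncertain.

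Coordinates are those of the authors' tables, on GRCm39. Symbols came from a GENCODE M21 table of gene names and were found for 51884 of 57126 gene identifiers (90.8%), which left 5242 without a symbol. Library depth ranged from 13703999 to 29136810 counts. The replicate files of a group held no identical values. The chi-square statistic per degree of freedom between libraries of one group was 2.708 to 91.06 over genes with at least 20 counts in the pair, above the sampling noise, so no library was taken as deposited more than once. Depth set the floor used here, 3 counts over a group, at 0.0426 CPM, the usual unit of counts scaled to library size, in untreated KPCh, 0.03698 in treated KPCh, 0.05527 in untreated iAKP and 0.05767 in treated iAKP. A fold against a group with 0 counts was computed against this floor and is a lower bound. A ratio resting on 1 to 3 counts is given with its exact 95% counting interval, and intervals and floors cover counting error only.

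Genes were filtered with filterByExpr over the 4 groups at its default minimum count of 10, which left 16587 genes. Counts were scaled by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust estimation, in one fit over the 12 libraries with a mean per group. The contrasts were treated against untreated KPCh, treated against untreated iAKP, and the difference, the iAKP effect minus the KPCh effect. The term edgeR adjusted p stands for the p of this quasi-likelihood test after Benjamini-Hochberg adjustment over the tested genes, and a gene rose or fell where it was under 0.05. CPM values are TMM-scaled and given as mean ± SD with n = 3, and log2 fold changes as value ± SE, the SE being the absolute log2 fold change divided by the square root of F. Calls were also counted among genes changed at least 2-fold.

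Designs, gene lists, naming rule and 9 kinds of alternative were fixed before the data were examined. The 30 lists were ERK transcriptional output, ERK immediate-early and feedback genes, RAS pathway components, G1/S and DNA replication, mitosis, CDK inhibitors and quiescence, p53 targets, MYC targets and ribosome biogenesis, glycolysis, cholesterol synthesis, lysosome and autophagy, receptor tyrosine kinases and adaptors, EGF family ligands, interferon response, MHC class I presentation, MHC class II presentation, cytokines and immune ligands, cholangiocyte markers, hepatocyte markers, epithelial junction genes, mesenchymal genes, fibroblast and stellate markers, immune cell markers, endothelial markers, YAP/TEAD targets, WNT targets, NOTCH pathway, BCL2 family, integrated stress response and NRF2 targets. They were written from textbook knowledge and held 520 entries for 509 symbols. Of these symbols 11 stood in more than 1 list, 1 (Rigi) was not matched to an identifier, and 43 entries were under the expression filter. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the 30 lists. It was tested again with the correlation estimated from the residuals of all 12 libraries. That estimate pooled KPCh and iAKP, whose spread was unequal, also for the contrasts of a single line. Camera asks whether a list moved more than the other genes. Members called are counted over all genes tested and also with p adjusted over the list alone, and a single count means that both were equal. In accounts of lists, a signed value after a gene name is its log2 fold change. The fry test, which asks whether a list's genes moved on balance one way, called 12 lists up and 11 down in KPCh, 9 up and 18 down in iAKP, and 4 up and 10 down in the difference.

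Named genes followed a rule. Kras, Hras, Nras, Trp53 and Ppia were always named. Per line, the 10 largest rises and the 10 largest falls were taken among protein-coding genes past the threshold with a mean of at least 10 CPM over the 6 libraries of that line and no overlap between treated and untreated libraries. For the difference, the 6 most positive and the 6 most negative genes past the threshold with a mean of at least 10 CPM in either line were taken. Per list, up to 4 members past the threshold with the largest changes were eligible, with up to 2 that did not pass or moved the other way. Predicted genes and genes without a symbol were left out.

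The code was tested on simulated counts for each comparison, with 200 changed genes in each line. With one spread for both lines, false calls were 7.1% of calls in KPCh, 8.6% in iAKP and 5.3% in the difference (16189 genes). The real lines had unequal spread, a common biological coefficient of variation of 18.5% in KPCh and 5.3% in iAKP against 13.7% jointly. With each line given its own spread and no pairing of libraries (16155 genes), 100 of 256 KPCh calls (39.1%), 1 of 152 iAKP calls (0.7%) and 19 of 256 difference calls (7.4%) were false. Such shares depend on the number of changed genes and do not carry over to the real calls. In that simulation the KPCh comparison recovered 44.8% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold. The iAKP comparison recovered 38.8%, 88.1% and 100%, and the difference 17.4%, 67.2% and 96.2%. With each line fitted alone, 14 of 135 KPCh calls (10.4%, 15169 genes) and 11 of 208 iAKP calls (5.3%, 14254 genes) were false. In the camera test on simulated counts, the changed list was called and 0 of 10 random lists were. The simulated genes were drawn independently, while the estimated correlation of the real mitosis list in KPCh was 0.959. That test therefore could not show false calls of lists whose genes move together.

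The replicate numbers in the titles (C1 to C3 and T1 to T3) were checked for pairing by correlating deviations from group means. In KPCh the same-numbered pairs correlated at 0.275, 0.21 and 0.257, all over the bound of 0.1, and the numbers were taken to pair the KPCh libraries. The alternatives were relative log expression scaling, library totals alone, no expression filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, each line fitted alone, the replicate number as a block, and each library left out in turn. An estimated correlation was the further alternative for camera. Its p is left out of all ranges of camera p over the alternatives. Restriction to genes without an exon overlap on the opposite strand was added after the file headers were read. Library totals in place of TMM shifted the median log2 fold change of all genes by 0.011 in KPCh, 0.187 in iAKP and 0.179 in the difference, and changes are stated relative to the TMM scale. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Protein levels, sequence variants and the mutant share of transcripts were not analysed here.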

Results

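Gene expression was measured by RNA-seq in the mouse cholangiocyte lines KPCh and iAKP, both labelled as mutant for KRAS and TP53. RMC-7977 is an inhibitor that binds cyclophilin A and, as a complex with it, GTP-bound RAS. The series was designed to find pathways altered by this inhibitor in cells related to cholangiocarcinoma, a cancer of the bile duct. Each line was sequenced untreated and after 24 h at 100 nM, with 3 libraries per group. Total counts per library were 17530994, 26057730 and 26577984 in untreated KPCh and 29136810, 25752575 and 25288703 in treated KPCh. They were 20046739, 18351719 and 20159363 in untreated iAKP and 17531553, 17951986 and 13703999 in treated iAKP. The 10 most abundant genes took 4.283% to 6.402% of the counts of a library. The first principal component held 74.4% of the variance and the next 16.5%.

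Kras itself (ENSMUSG00000030265.15, chromosome 6, 145162425 to 145195965, minus strand, GRCm39) was measured in every library. In KPCh it stood at 136.51, 137.4 and 147.61 CPM untreated and 144.84, 188.96 and 158.43 CPM treated (log2 fold change 0.22 ± 0.11, edgeR adjusted p = 0.12). In iAKP it stood at 2157.66, 2086.99 and 2340.17 CPM untreated and fell to 1440.73, 1361.14 and 1412.05 CPM (−0.64 ± 0.11, edgeR adjusted p = 0.000135). Trp53 (ENSMUSG00000059552.14, chromosome 11, 69471185 to 69482699, plus strand) was at 13.84, 10.53 and 11.71 CPM in untreated and 13.3, 7.88 and 9.76 CPM in treated KPCh, without a call (edgeR adjusted p = 0.368). In iAKP it was at 4.91, 5.33 and 4.39 CPM untreated and 5.99, 6.66 and 6.02 CPM treated (edgeR adjusted p = 0.136, and 0.0265 to 0.287 over the alternatives). Ppia, which encodes cyclophilin A (ENSMUSG00000071866.13, chromosome 11, 6365443 to 6369817, plus strand), fell in iAKP from 828.2, 712.04 and 686.97 to 400.93, 373.36 and 368.26 CPM (−0.96, edgeR adjusted p = 1.65e-05). In KPCh Ppia was at 516.09, 414.1 and 521.23 CPM untreated and 385.24, 306.41 and 421.58 CPM treated (−0.38), a fall whose edgeR adjusted p of 0.0283 ranged from 0.000779 to 0.0916 over the alternatives. Hras and Nras had KPCh log2 fold changes of −0.42 (edgeR adjusted p = 0.0179) and −0.22 (0.0351), and both calls ended when the line was fitted alone (0.0711 and 0.109, with ranges of 0.00116 to 0.0711 and 0.0125 to 0.258 over the alternatives). In iAKP the edgeR adjusted p was 0.314 for Hras and 0.152 for Nras, and the Nras call was gained in iAKP alone (0.033, range 0.033 to 0.79).

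The KPCh comparison asked which genes responded to RMC-7977 in that line. Of the transcriptional output genes of ERK, the kinase at the end of the RAS pathway, 9 of 10 fell, as did 5 of 8 EGF family ligands, 23 of 24 MYC target and ribosome biogenesis genes, 17 of 25 G1/S genes and 12 of 25 mitosis genes. Camera called these 5 lists lower, and with an estimated correlation the EGF ligands kept the call (adjusted p = 0.0154) while the others lost it (adjusted p = 0.137 for ERK output, 0.495 for MYC targets and for G1/S, and 0.516 for mitosis with an estimated correlation). Sprouty gene Spry4, a feedback inhibitor of receptor signalling (ENSMUSG00000024427.8, chromosome 18, 38719300 to 38734468, minus strand), fell from 24.9 ± 1.08 to 1.61 ± 1.41 CPM (SD, n = 3). The EGF receptor ligand Areg (ENSMUSG00000029378.6, chromosome 5, 91287458 to 91296291, plus strand) fell from 30.8 ± 1.87 to 0.926 ± 0.398 CPM. Of interferon response genes 17 of 23 rose, of lysosome and autophagy genes 14 of 25 rose and 1 fell, and of epithelial junction genes 10 of 18 rose. Camera called these 3 lists higher, and all lost the call with an estimated correlation (adjusted p = 0.137, 0.495 and 0.495 with an estimated correlation). The pro-apoptotic gene Bmf (ENSMUSG00000040093.17, chromosome 2, 118359238 to 118380168, minus strand) rose from 4.61 ± 1.27 to 93.1 ± 19.4 CPM. Mitochondrial genes took 4.087%, 3.917% and 2.959% of counts in untreated KPCh libraries 1, 2 and 3 and more in the treated library of each number, 5.026%, 4.671% and 3.93%. Of 16587 genes, 3563 were higher and 3095 lower (40.1% in all), and 1379 of the higher and 766 of the lower changed at least 2-fold. In the simulation with each line's own spread, which left the pairing of the KPCh libraries out, 39.1% of KPCh calls were false, so part of the calls of small fold may be false. With KPCh fitted alone 2158 genes were higher and 2017 lower, and 4129 of those 4175 were among the 6658 of the joint fit. That fit also left the pairing out, and with the replicate block in the joint fit 3928 genes were higher and 3634 lower.

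The largest KPCh rises under the naming rule were the phosphate transporter gene Slc34a2 (ENSMUSG00000029188.15, chromosome 5, 53195423 to 53229006, plus strand; 1.8 ± 0.707 to 59.8 ± 34.4 CPM, log2 fold change 5.06 ± 0.50, edgeR adjusted p = 0.000128) and the transcription factor gene Sox8 (ENSMUSG00000024176.12, chromosome 17, 25784634 to 25789726, minus strand; 1.03 ± 0.49 to 33.5 ± 10.2 CPM, 4.98 ± 0.31, 9.79e-08). The secreted siderophore-binding protein gene Lcn2 (ENSMUSG00000026822.15, chromosome 2, 32274645 to 32278264, minus strand) rose from 11.1 ± 4.74 to 298.7 ± 90.8 CPM (4.75 ± 0.33, edgeR adjusted p = 3.17e-06). Bmf rose by 4.31 ± 0.19 (edgeR adjusted p = 5.12e-09). The amine oxidase gene Aoc1 (4.94), the alkaline phosphatase gene Alpl (4.86), complement gene C3 (4.43), Nrep (4.06), the sugar transporter gene Slc5a9 (4.06) and the carboxylate transporter gene Slc13a2 (3.90) completed the 10. Their treated means were 24.6, 24.9, 39.7, 52.7, 54.8 and 26.1 CPM.

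The largest KPCh falls under the naming rule were those of the mast cell protease gene Mcpt8 (23.5 ± 8.68 to 0.636 ± 0.529 CPM, −5.15 ± 0.40, edgeR adjusted p = 1.3e-06) and of Areg (−5.02 ± 0.21, 4.4e-09). The mannose receptor gene Mrc1 fell from 116.6 ± 26.3 to 4.4 ± 2.25 CPM (−4.72) and the placental hormone gene Prl2c2 from 24.2 to 1.12 CPM (−4.43, edgeR adjusted p = 5.19e-05). Il5ra, which encodes the interleukin-5 receptor alpha chain (ENSMUSG00000005364.12, chromosome 6, 106687318 to 106725998, minus strand), fell from 498.5 ± 14.6 to 41.6 ± 10.7 CPM (−3.58 ± 0.17, edgeR adjusted p = 7.74e-09). Spry4 (−3.91), the troponin gene Tnnt2 (−3.73), Tnfaip2 (−3.38), the immune checkpoint receptor gene Tigit (−3.33) and the ERK-induced transcription factor gene Etv5 (−3.29) completed the 10. All 20 of these rises and falls kept their call with KPCh fitted alone.

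Of the 10 ERK transcriptional output genes, 9 fell in KPCh and none rose (9 lower adjusted over the list alone; median −1.97; camera adjusted p = 3e-09, and adjusted p = 0.137 with an estimated correlation). Dusp6, an ERK phosphatase (ENSMUSG00000019960.9, chromosome 10, 99099093 to 99103351, plus strand), fell from 152.7 ± 6.57 to 25.5 ± 15.1 CPM (−2.58 ± 0.38, edgeR adjusted p = 0.000481). Etv5 (ENSMUSG00000013089.16, chromosome 16, 22200059 to 22258469, minus strand) fell from 53.6 ± 8.11 to 5.42 ± 4.48 CPM, and Etv4 by 2.99 on the log2 scale, while Epha4 had a change of −0.19 (edgeR adjusted p = 0.38). Among 18 ERK immediate-early and feedback genes, 14 fell and 2 rose, the same counts adjusted over the list alone, with 12 of 17 lower and 0 higher when KPCh was fitted alone (median −0.91; camera adjusted p = 1.5e-10, and adjusted p = 0.0154 with an estimated correlation). The chromatin protein gene Hmga2 fell from 438 to 48.3 CPM (−3.18, edgeR adjusted p = 7.57e-10), while the phosphatase gene Dusp1 (1.10) and the mRNA decay factor gene Zfp36 (0.62) rose. Neither rise was called with KPCh fitted alone or without treated library 2, and 1 list member was higher without treated library 1. All 5 EGF family ligands that changed fell, of 8 measured, also adjusted over the list alone (median −1.06; camera adjusted p = 4.08e-11, and adjusted p = 0.0154 with an estimated correlation). Btc was at −2.93, Ereg at −2.49 and Tgfa at −1.11 beside Areg. The treated libraries were unequal, and their median over the ERK output list was −1.55, −2.91 and −1.83 in treated libraries 1, 2 and 3.

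Of 25 G1/S and DNA replication genes 17 fell (24 adjusted over the list alone; median −1.05; camera adjusted p = 1.17e-06, and adjusted p = 0.495 with an estimated correlation), among them the thymidine kinase gene Tk1 (126.2 to 45.9 CPM, −1.46, edgeR adjusted p = 0.00391), Gins1 (−1.47) and E2f2 (−1.44). Of 25 mitosis genes 12 fell (15 adjusted over the list alone; median −0.97; camera adjusted p = 1.7e-05, and adjusted p = 0.516 with an estimated correlation). Ube2c was at −1.45 (edgeR adjusted p = 0.00791), and with the replicate block 21 mitosis genes fell. Library medians over treated libraries 1, 2 and 3 were −0.76, −2.22 and −0.54 for G1/S, −0.97, −2.35 and −0.30 for mitosis and −0.65, −1.28 and −0.67 for MYC targets. With KPCh fitted alone 4 G1/S and 1 mitosis genes fell, and without treated library 1, 2 or 3 the mitosis count was 6, 21 or 25. Of 24 MYC targets and ribosome biogenesis genes 23 fell (24 adjusted over the list alone; median −0.85; camera adjusted p = 6.17e-12, and adjusted p = 0.495 with an estimated correlation). The polyamine enzyme gene Odc1 was at −1.49 and Srm at −1.41. Of 19 integrated stress response genes 9 fell, also adjusted over the list alone (median −0.75; camera adjusted p = 8.25e-05, and adjusted p = 0.495 with an estimated correlation). The serine synthesis gene Psat1 went from 460 to 159.5 CPM and the cystine transporter gene Slc7a11 was at −2.78. Of 16 glycolysis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; median −0.63; camera adjusted p = 0.000259, and adjusted p = 0.495 with an estimated correlation). The lactate dehydrogenase gene Ldha was at −1.06 and Pfkfb3 at 0.62.

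Of 23 interferon response genes 17 rose and none fell (18 adjusted over the list alone, 9 with the line fitted alone; median 1.18; camera adjusted p = 1.17e-05, and adjusted p = 0.137 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose from 0.351 to 3.92 CPM (3.44), Ifit3 by 3.07 and Rtp4 by 2.04. Of 25 lysosome and autophagy genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.48; camera adjusted p = 0.00118, and adjusted p = 0.495 with an estimated correlation). The autophagosome gene Map1lc3a was at 1.05, Hexa at 1.00 and the regulator Tfeb at −0.47. Of 18 epithelial junction genes 10 rose and none fell (11 adjusted over the list alone; median 0.47; camera adjusted p = 0.00499, and adjusted p = 0.495 with an estimated correlation). The desmosome gene Dsp went from 247 to 613.5 CPM (1.31). Of 22 YAP/TEAD targets 8 rose and 4 fell, also adjusted over the list alone (median 0.19; camera adjusted p = 0.034, and adjusted p = 0.495 with an estimated correlation). Nt5e was at 2.78, Tgfb2 at 2.72 and Igfbp3 at −2.71. The camera adjusted p of the YAP/TEAD list ranged from 0.00976 to 0.312 over the other alternatives and was 0.0961 with the replicate block, and that of the epithelial junction list from 8.72e-05 to 0.107. For the other 10 called lists it stayed between 4.07e-29 and 0.0187.

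Lists without a camera call in KPCh included single strong changes. Receptor tyrosine kinases and adaptors had 9 genes higher and 4 lower of 19 (10 and 4 adjusted over the list alone, 4 higher with the line alone; median 0.50, or 0.45 with 1 gene near the floor left out; camera adjusted p = 0.128, ranging from 0.035 to 0.722 over the alternatives). Among them were the FGF receptor genes Fgfr3 (11.0 to 60.7 CPM, 2.47) and Fgfr2 (17.2 to 85.8 CPM, 2.32). The CDK inhibitors and quiescence list had 7 higher and 2 lower of 18 (8 and 2 adjusted over the list alone; median 0.09; 0.243). Cdkn1a was at 1.07 (edgeR adjusted p = 0.00148). The p53 targets had 7 higher and 3 lower of 20 (7 and 4 adjusted over the list alone; camera adjusted p = 0.457), with a median of −0.02 but a mean of 0.33, and Pmaip1 at 2.21. The BCL2 family had 6 higher and 3 lower of 15 (median 0.02, 0.255). Bcl2 was at −0.96. Cholesterol synthesis had 4 lower of 20 (3 adjusted over the list alone, 9 with the replicate block; median −0.16, 0.138). Pcsk9 was at −1.13 (edgeR adjusted p = 0.00509). The camera p of this list ranged from 0.00875 to 0.462 over the alternatives, and was 0.617 with an estimated correlation. MHC class I presentation had 6 higher and 1 lower of 13 (7 and 1 adjusted over the list alone, 3 higher with the line alone; median 0.41), and its camera adjusted p of 0.0535 was 0.0313 with the replicate block, in a range of 0.00703 to 0.288. MHC class II presentation had 1 of 2 genes higher (camera adjusted p = 0.441), Cd74 at 2.41. Cytokines and immune ligands had 7 higher and 6 lower of 21 (7 and 7 adjusted over the list alone; median 0.24; 0.632). Ccl2 went from 14.3 to 97.4 CPM, Csf2 from 13.3 to 1.15 CPM, and Ccl7 from 0 to 68 counts, at least 19.6-fold higher.

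Markers of cell identity and other pathways completed the KPCh lists. Cholangiocyte markers had 8 higher and 2 lower of 18 (median 0.26; camera adjusted p = 0.179). Cd24a went from 330.5 to 794 CPM and the secreted phosphoprotein gene Spp1 was at −0.07 (edgeR adjusted p = 0.782). Hepatocyte markers had 3 higher and 1 lower of 11 (0.422), with a median of 0.00 (−0.10 with 2 genes near the floor left out), a mean of 0.36 and the transthyretin gene Ttr at 3.30. Mesenchymal genes had 4 higher and 5 lower of 19 (median −0.13, 0.685). Tgfbi was at 3.45 and the vimentin gene Vim went from 1269 to 524 CPM. Fibroblast and stellate markers had 2 higher of 6 (median 1.19, or 1.155 with 1 gene near the floor left out; 0.354), Col1a1 at 1.22. Of these markers, Col3a1 had no counts in untreated KPCh. Dcn had 1 untreated and 8 treated counts, a ratio of 6.945 with a counting interval of 0.9311 to 308.2. Immune cell markers had 1 of 5 higher (median 0.46, 0.446) and endothelial markers 1 of 2 lower (median −1.44, 0.361). RAS pathway components had 1 higher and 5 lower of 20 (0 and 4 adjusted over the list alone, 2 lower with the line alone; median −0.01, 0.204). The scaffold gene Ksr1 was at −1.01. WNT targets had 2 higher and 3 lower of 8 (median −0.53, 0.153). Apcdd1 was at −2.19. NRF2 targets had 1 higher and 4 lower of 15 (median −0.08; 0.179, ranging from 0.0197 to 0.289 over the alternatives). The NOTCH pathway had 5 higher and 4 lower of 11 (5 and 5 adjusted over the list alone; camera adjusted p = 0.546, direction down against a median of 0.05 and a mean of 0.19). The ligand gene Dll4 went from 119.9 to 18.2 CPM and Notch3 was at 2.28.

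**Figure D1:**
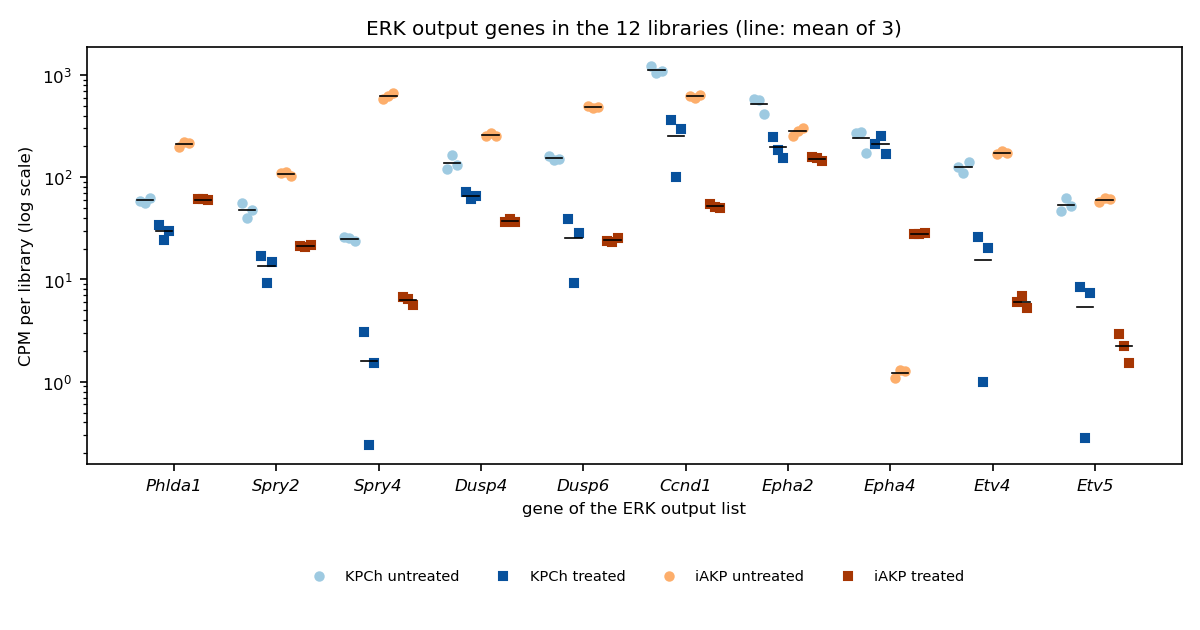
TMM-scaled CPM per library on a log axis for the ERK output genes in the 12 libraries, with points for single libraries and short horizontal lines for the mean of 3. Treated points lie below untreated points for 9 of the 10 genes in each line, and Epha4 rose in iAKP.

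The iAKP comparison asked the same of that line, where libraries of a group differed less. Of the ERK output genes 9 of 10 fell and 1 rose, all 20 cholesterol synthesis genes fell, and all 25 mitosis genes fell. Camera called these 3 lists lower, and all lost the call with an estimated correlation (adjusted p = 0.339, 0.0673 and 0.492 with an estimated correlation). That correlation was estimated over the libraries of both lines, including the more variable KPCh libraries. An estimate from the iAKP libraries alone was not made. Spry4 fell from 625 ± 44.5 to 6.28 ± 0.609 CPM (SD, n = 3). The ketone body synthesis gene Hmgcs2 (ENSMUSG00000027875.13, chromosome 3, 98187751 to 98218054, plus strand) rose from 2.18 ± 0.387 to 189.6 ± 3.62 CPM, and the fibrillar collagen gene Col3a1 (ENSMUSG00000026043.19, chromosome 1, 45350698 to 45388866, plus strand) from 5.07 ± 0.779 to 290.8 ± 17 CPM. Mitochondrial genes took 1.613%, 0.82% and 1.037% of counts in untreated and 1.595%, 1.736% and 1.689% in treated iAKP libraries. Of 16587 genes 5212 were higher and 5140 lower (62.4% in all), and 2776 of the higher and 2227 of the lower changed at least 2-fold. The share of higher genes among the calls was 50.3%, and 62.2% with library totals as the scaling.

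The largest iAKP rises under the naming rule were those of Hmgcs2 (log2 fold change 6.43 ± 0.21, edgeR adjusted p = 6.11e-11), the acute phase gene Saa3 (7.14 ± 1.33 to 509 ± 29.8 CPM, 6.15 ± 0.16, 3.67e-11), the integrin gene Itgb8 (5.96) and Col3a1 (5.84 ± 0.14, 2.88e-11). They were followed by the TGF-beta ligand gene Tgfb2 (0.767 to 35.6 CPM, 5.52), the transcription factor gene Atoh8 (5.50), the collagen prolyl hydroxylase gene P4ha3 (5.37), Kcnu1 (5.33), Fbln7 (5.17) and the haptoglobin gene Hp (6.19 to 221.5 CPM, 5.16). The largest falls under that rule were those of the leukocyte receptor gene Lilr4b (56.7 ± 0.744 to 0.342 ± 0.194 CPM, −7.41, edgeR adjusted p = 8.08e-10), Spry4 (−6.63 ± 0.43, 3.81e-07) and the apolipoprotein gene Apoa1 (ENSMUSG00000032083.9, chromosome 9, 46139878 to 46141764, plus strand; 311.8 ± 26.7 to 4.91 ± 0.566 CPM, −5.98 ± 0.18, 2.71e-11). Nckap1l (−5.79), the cytokine gene Il11 (63.5 to 1.14 CPM, −5.78), Tecta (−5.50), Il5ra (−5.45), the protease gene Prss22 (−5.22), Areg (302.2 ± 11.7 to 8.39 ± 2.03 CPM, −5.17) and Etv4 (173.7 ± 6.91 to 6.01 ± 0.81 CPM, −4.84) completed the 10.

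Of the 10 ERK transcriptional output genes 9 fell in iAKP and 1 rose, also adjusted over the list alone (median −3.18; camera adjusted p = 5.02e-05, and adjusted p = 0.339 with an estimated correlation). Dusp6 fell from 485.6 to 24.2 CPM (−4.33) and Etv5 from 60.1 ± 2.43 to 2.24 ± 0.719 CPM, while the ephrin receptor gene Epha4 rose from 1.22 to 28.0 CPM (4.52, edgeR adjusted p = 6.53e-09). Of 18 ERK immediate-early and feedback genes 15 fell, also adjusted over the list alone (median −1.25; camera adjusted p = 1.56e-06, and adjusted p = 0.0538 with an estimated correlation). Egr1 was at −3.63 and Spry1 at −2.87. Of 8 EGF family ligands 6 fell and Egf rose by 1.20, the same adjusted over the list alone (median −1.53; camera adjusted p = 1.24e-07, and adjusted p = 0.0472 with an estimated correlation). Btc was at −3.80 and Hbegf at −2.64. The G1/S and DNA replication genes fell in 23 of 25 (median −1.57; camera adjusted p = 0.000314, and adjusted p = 0.619 with an estimated correlation), Tk1 from 144 to 20.5 CPM. The mitosis list (median −2.38; camera adjusted p = 6.84e-07, and adjusted p = 0.492 with an estimated correlation) included the topoisomerase gene Top2a, from 1116 to 173.2 CPM, and the spindle checkpoint gene Bub1, from 229 to 26.3 CPM. MYC targets and ribosome biogenesis genes fell in 23 of 24 (median −0.97; camera adjusted p = 8.54e-07, and adjusted p = 0.468 with an estimated correlation). Odc1 was at −2.62. The member counts of these 3 lists were the same adjusted over the list alone.

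The cholesterol synthesis list fell in all 20 members, also adjusted over the list alone (median −2.04; camera adjusted p = 8.49e-19, and adjusted p = 0.0673 with an estimated correlation). The sterol methyl oxidase gene Msmo1 (ENSMUSG00000031604.11, chromosome 8, 65171173 to 65186826, minus strand) fell from 266.5 ± 14.8 to 21.5 ± 1.17 CPM (−3.63, edgeR adjusted p = 2.71e-11), the farnesyl diphosphate synthase gene Fdps from 225 to 23.5 CPM (−3.26) and the LDL receptor regulator gene Pcsk9 from 281 to 33.1 CPM (−3.09). Of 19 integrated stress response genes 13 fell and none rose, also adjusted over the list alone (median −1.28; camera adjusted p = 4.42e-06, and adjusted p = 0.375 with an estimated correlation). Mthfd2 was at −2.81, Psat1 at −2.75 and Psph at −2.16. Lysosome and autophagy genes had 13 higher and 3 lower of 25 (median 0.31; camera adjusted p = 0.0321, and adjusted p = 0.62 with an estimated correlation). The saposin precursor gene Psap went from 404 to 1130 CPM. Receptor tyrosine kinases and adaptors had 10 higher and 1 lower of 19 (median 0.49; camera adjusted p = 0.00372, and adjusted p = 0.398 with an estimated correlation). Their Fgfr2 went from 2 to 156 counts over the group, a ratio of 81.4 with a counting interval of 22.2 to 678.0, Pdgfrb rose by 2.26, the insulin receptor substrate gene Irs1 by 2.11 and the receptor gene Erbb2 from 27.3 to 90.1 CPM.

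Of 6 fibroblast and stellate markers 5 rose in iAKP, also adjusted over the list alone (median 2.98; camera adjusted p = 6.21e-07, and adjusted p = 0.0189 with an estimated correlation), while Postn, Col1a2, Lum, Thy1, Lrat and Des of the same list failed the filter and were not tested. Col1a1 went from 2.79 to 43.8 CPM (3.98, edgeR adjusted p = 8.42e-08), and Dcn was at 3.69 beside Col3a1. Of 19 mesenchymal genes 11 rose and 5 fell, also adjusted over the list alone (median 1.17; camera adjusted p = 0.000747, and adjusted p = 0.0673 with an estimated correlation). The smooth muscle actin gene Acta2 went from 0 to 856 counts, at least 295.6-fold higher. Tgfbi rose by 3.29 and Sparc by 2.34, and Vim fell by 1.19. Of 22 YAP/TEAD targets 11 rose and 4 fell (median 0.37; camera adjusted p = 0.00128, and adjusted p = 0.375 with an estimated correlation). Ccdc80 was at 6.42 and Nt5e at −1.71, and Amotl2 went from 10.9 to 124.7 CPM. Interferon response genes had 12 higher and 2 lower of 23 (median 0.43; camera adjusted p = 0.0264, and adjusted p = 0.398 with an estimated correlation). Gbp2 went from 1.53 to 46.9 CPM, and Xaf1 was at 3.22 and Rsad2 at −2.60. The interferon camera p ranged from 0.00506 to 0.0802 over the other alternatives, and that of the other 13 called lists from 1.17e-46 to 0.0412.

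The remaining iAKP lists had no camera call. Epithelial junction genes had 9 higher and 1 lower of 18 (median 0.63; camera adjusted p = 0.146, ranging from 0.0161 to 0.27 over the alternatives). The claudin gene Cldn7 was at 2.01. Cytokines and immune ligands had 6 higher and 10 lower of 21 (median −0.54; 0.056, ranging from 0.0149 to 0.432 over the alternatives). The colony stimulating factor gene Csf1 rose from 54.5 to 553.5 CPM and the alarmin gene Il33 fell from 73.7 to 5.48 CPM (−3.75, edgeR adjusted p = 7.58e-12). Cholangiocyte markers had 7 higher and 8 lower of 18 (median −0.38, or −0.42 with 1 gene near the floor left out, mean 0.20; camera adjusted p = 0.454). Spp1 fell from 3006 to 460 CPM (−2.71) and the biliary transcription factor gene Sox9 from 378 to 87.1 CPM (−2.12). Hepatocyte markers had 3 higher and 4 lower of 11 (median 0.05, mean −0.68, direction down; camera adjusted p = 0.086, ranging from 0.0198 to 0.692 over the alternatives), the transferrin gene Trf going from 6798 to 1237 CPM. Glycolysis had 2 higher and 6 lower of 16 (5 lower adjusted over the list alone; median −0.26, 0.632). The regulator Pfkfb3 rose from 129.5 to 333.8 CPM, and with the line alone 11 glycolysis genes fell. RAS pathway components had 4 higher and 7 lower of 20 (median −0.13, 0.552). Rasal1 was at −2.33 and the phosphatase gene Ptpn11 at 0.69. CDK inhibitors and quiescence had 4 higher and 8 lower of 18 (median −0.05, 0.454). Cdkn1a was at −1.04 and Mxd4 at 1.51. The p53 targets had 4 higher and 7 lower of 20 (median −0.10, 0.546). The death receptor gene Fas was at 3.10. MHC class I presentation had 5 higher of 13 (4 adjusted over the list alone; median 0.27, 0.33). Tapbp was at 1.22. MHC class II presentation had 2 of 2 higher (median 1.81, 0.33). Immune cell markers had 1 higher and 1 lower of 5 (median −0.55, 0.552). Fcer1g was at −1.97. Endothelial markers fell in 2 of 2 (median −3.18; 0.0604, ranging from 0.0254 to 0.501), Cdh5 at −4.06 and Pecam1 at −2.29. WNT targets had 2 higher and 4 lower of 8 (median −0.38, mean 0.47, 0.392). Notum was at 2.95. The NOTCH pathway had 2 higher and 5 lower of 11 (median −0.34; 0.0651, ranging from 0.023 to 0.234 over the alternatives). Jag1 was at −2.70. The BCL2 family had 6 higher and 6 lower of 15 (median 0.14, mean −0.13, direction down, 0.546). Bcl2l1 was at −1.62 and Bcl2 at 1.21. NRF2 targets had 4 higher and 9 lower of 15 (median −0.46; 0.0908, ranging from 0.0211 to 0.227 over the alternatives). Osgin1 was at −2.38.

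**Figure D2:**
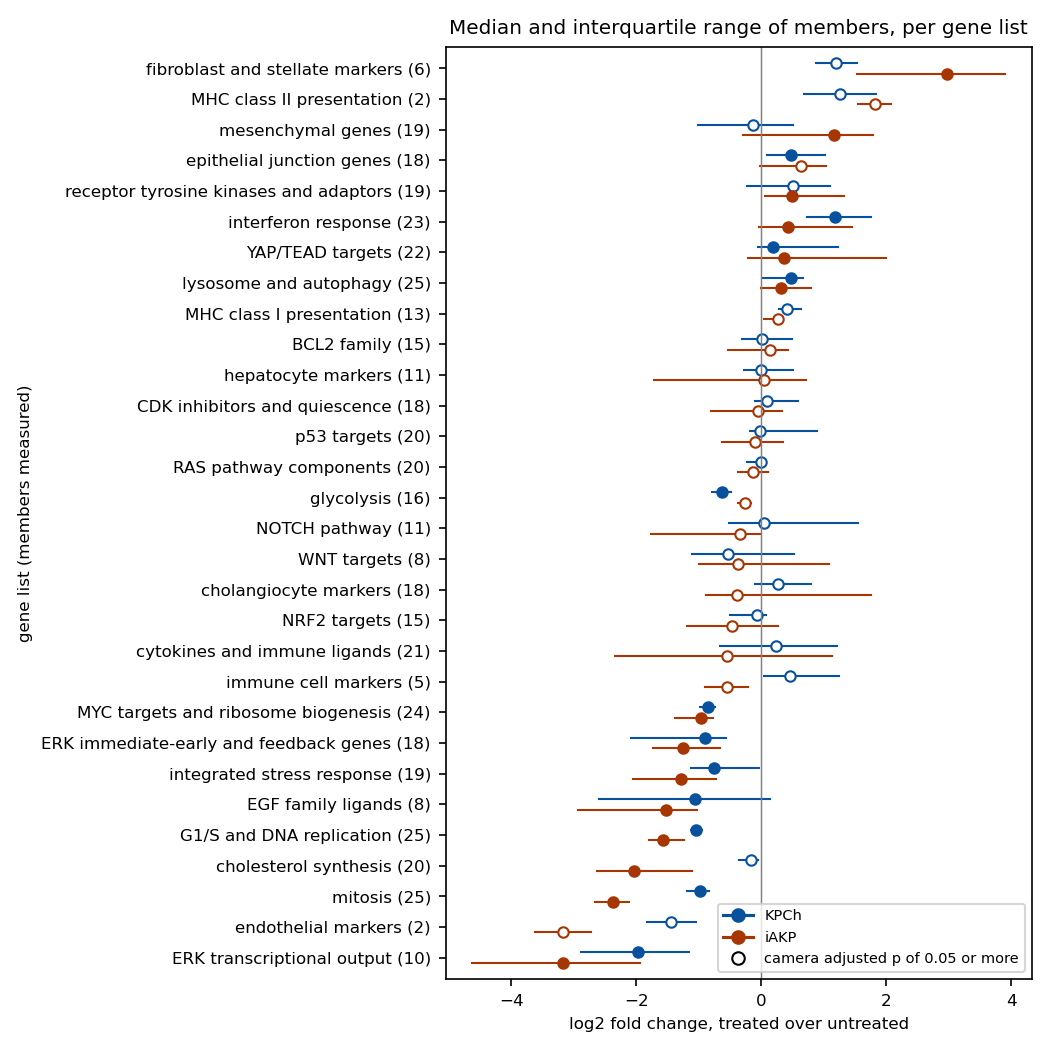
Median (point) and interquartile range (bar) of the log2 fold change, treated over untreated, over the measured members of each gene list in KPCh and iAKP, with the number of members on the list axis and open points for a camera adjusted p of 0.05 or more. The ERK output medians were −1.97 in KPCh and −3.18 in iAKP, and the cholesterol synthesis medians −0.16 and −2.04.

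The responses of both lines were compared gene by gene, and these comparisons share no control libraries. They came from one fit with shared dispersion estimates, however, so the calls of the lines are not independent. The numbers for independent lists are therefore only a reference. Genes higher in both lines numbered 2231, where independent lists of these sizes would share 1119.6, and genes lower in both numbered 2318 against 959.1. In opposite directions, 240 genes were higher in KPCh and lower in iAKP (1104.1 for independent lists) and 207 the other way (972.5). Of the 4996 genes past the threshold in both lines 91.1% had the same sign. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson 0.484 and Spearman 0.555. The Pearson value depended on the filter, at 0.221 with no expression filter and 0.592 at a mean of at least 5 CPM. Areg fell in both (−5.02 and −5.17), as did Il5ra (−3.58 and −5.45), Mrc1 (−4.72 and −3.08) and Mcpt8 (−5.15 and −4.80). Nrep (4.06 and 3.25), C3 (4.43 and 2.95), Lcn2 (4.75 and 2.21) and Aoc1 (4.94 and 3.26) rose in both. With each line fitted alone, 1411 genes were higher in both and 277 changed in opposite directions.

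The difference between the lines was tested as the iAKP effect minus the KPCh effect, and line cannot be told apart here from batch label and from strand setting of the counting. Cholesterol synthesis genes fell further in iAKP than in KPCh in 19 of 20 members (20 adjusted over the list alone; median −1.94; camera adjusted p = 1.92e-28, and adjusted p = 0.101 with an estimated correlation). Fdps was at 182 and 173 CPM in untreated and treated KPCh (−0.08, edgeR adjusted p = 0.718), and its difference was −3.19 (edgeR adjusted p = 2.85e-07), that of Msmo1 −3.29 and that of Cyp51 −2.86. Mitosis genes fell further in iAKP in 10 of 25 (16 adjusted over the list alone; median −1.33; camera adjusted p = 0.00274, and adjusted p = 0.712 with an estimated correlation), and in 2, 24 and 6 without KPCh treated library 1, 2 and 3. Of 16587 genes 2518 had a positive and 2738 a negative difference (31.7% in all), and 1352 and 1105 of them differed at least 2-fold. The negative count was 1738 without iAKP untreated library 1 and 1785 without untreated library 3. Kras had a difference of −0.87 (edgeR adjusted p = 0.000779) and Ppia of −0.58, whose edgeR adjusted p of 0.0253 ranged from 0.00086 to 0.147 over the alternatives. The positive share of the called differences was 47.9%, and 67.6% with library totals as the scaling, under which 1701 genes were negative.

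**Figure D3:**
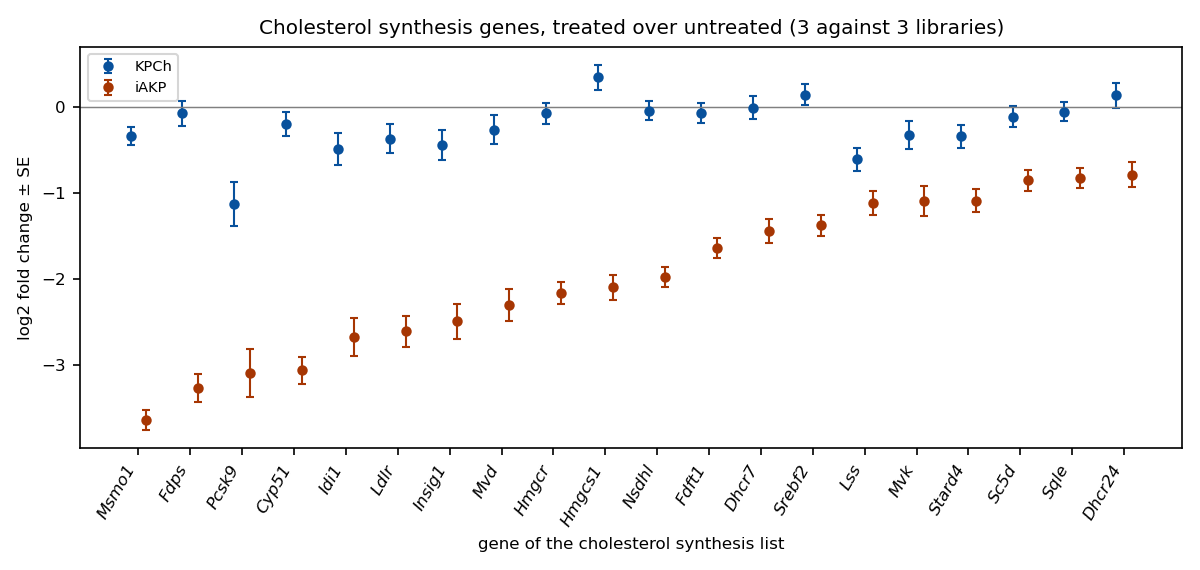
Log2 fold change ± SE, treated over untreated with 3 against 3 libraries, for each cholesterol synthesis gene in KPCh and iAKP. All 20 genes lie under 0 in iAKP, where Msmo1 is at −3.63, while Fdps is at −0.08 in KPCh.

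The most positive difference under the naming rule was that of the BMP antagonist gene Grem1 (ENSMUSG00000074934.4, chromosome 2, 113576509 to 113588991, minus strand), which fell from 14.1 ± 6.57 to 1.97 ± 1.09 CPM in KPCh and rose from 45.7 ± 1.48 to 814.6 ± 45.5 CPM in iAKP (difference 6.94 ± 0.49, edgeR adjusted p = 4.81e-06). Galnt18 rose by 5.14 in iAKP (1.79 to 62.8 CPM), with −0.76 in KPCh (edgeR adjusted p = 0.279) and an edgeR adjusted p of 1.2e-05 for the difference. The heparan sulfatase gene Sulf2 fell in KPCh (−1.39) and rose in iAKP from 1.78 to 37.2 CPM (4.38). The protease gene Adamts5 rose in KPCh from 17.6 to 62.2 CPM and in iAKP went from 0 to 94 counts, at least 32.6-fold higher. The water channel gene Aqp8 went from 558 to 1 counts in KPCh, a ratio of 0.00156 with a counting interval of 3.93e-05 to 0.0087, and fell in iAKP from 47.1 to 6.12 CPM. Spata20 was at 13.1 and 15.3 CPM in KPCh (edgeR adjusted p = 0.395) and went from 0 to 14 counts in iAKP, at least 4.68-fold higher. On the negative side, the actin-severing protein gene Scin (ENSMUSG00000002565.17, chromosome 12, 40109768 to 40184227, minus strand) rose from 52.5 ± 14.4 to 196 ± 40.7 CPM in KPCh and fell from 9.6 ± 0.792 to 0.405 ± 0.0347 CPM in iAKP (difference −6.45 ± 0.37, edgeR adjusted p = 1.77e-07). The stress cytokine gene Gdf15 was at 253 and 254 CPM in KPCh and fell from 10.1 to 0.141 CPM in iAKP (−5.99). Sox8 had 11 and 3 counts in iAKP, a ratio of 0.285 with a counting interval of 0.051 to 1.08. Apoa1 stood at 0.184 and 0.153 CPM in KPCh. Nckap1l and Tecta, the others of the 6, had 2 untreated and 3 treated counts each in KPCh, at or under the floor, and without KPCh treated library 1 the edgeR adjusted p of their differences went from 0.00526 to 0.909 and from 0.00589 to 0.897, with ranges of 5.4e-05 to 0.909 and 0.000156 to 0.897 over the alternatives.

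Other lists differed between the lines. Mesenchymal genes were more positive in iAKP (9 of 19 positive, 1 negative, 10 and 1 adjusted over the list alone; median 0.66; camera adjusted p = 0.00274, and adjusted p = 0.101 with an estimated correlation), as were YAP/TEAD targets (11 positive and 3 negative of 22, 11 and 6 adjusted over the list alone; median 0.52; 0.0123, and adjusted p = 0.592 with an estimated correlation). Receptor tyrosine kinases and adaptors (7 positive and 2 negative of 19, the latter 5 with the replicate block; median 0.40; camera adjusted p = 0.0421, and adjusted p = 0.617 with an estimated correlation) included Irs1 at 2.60 and Fgfr3 at −3.01. Glycolysis (5 positive of 16, or 9 with the replicate block; median 0.45; camera adjusted p = 0.0421, and adjusted p = 0.693 with an estimated correlation) was also more positive. Cytokines and immune ligands were more negative (3 positive and 11 negative of 21, 4 and 13 adjusted over the list alone; median −1.27; camera adjusted p = 0.00274, and adjusted p = 0.592 with an estimated correlation). Il11 was at −4.53 and Il33 at −3.35. Integrated stress response genes were more negative in 7 of 19 (median −0.76; camera adjusted p = 0.00648, and adjusted p = 0.624 with an estimated correlation), NOTCH pathway genes in 5 of 11 with 2 positive (median −0.74; 0.0421, and adjusted p = 0.4 with an estimated correlation), and CDK inhibitors and quiescence genes in 7 of 18 with 2 positive (median −0.24; 0.0421, and adjusted p = 0.592 with an estimated correlation). Cdkn1a had a difference of −2.11 and Bcl2 of 2.17 (edgeR adjusted p = 0.000193 and 0.000468). With the replicate block the receptor, NOTCH and CDK inhibitor calls ended (camera adjusted p = 0.0964, 0.0697 and 0.0697). Over all alternatives but the estimated correlation, camera p ranged from 0.0183 to 0.145 for the receptor list, 0.00562 to 0.181 for NOTCH, 0.013 to 0.145 for CDK inhibitors, 0.00277 to 0.108 for glycolysis and 0.000124 to 0.0636 for mesenchymal genes, and stayed between 7.54e-36 and 0.0489 for the other 5 called lists. The ERK output list had 1 positive and 5 negative of 10 (2 and 5 adjusted over the list alone; median −1.43; camera adjusted p = 0.422), and without KPCh treated library 2 its p was 1.09e-07, in a range of 1.09e-07 to 0.834. The G1/S list had 1 positive and 1 negative of 25 (median −0.45, 0.422), and 19 negative without that library, where its p was 4.81e-08, in a range of 4.81e-08 to 0.993. For the 20 lists without a call the camera adjusted p of the difference lay between 0.0565 and 0.977. Some of them gained a call under an alternative other than the estimated correlation. Beside ERK output and G1/S these were MYC targets (0.0174 without KPCh treated library 2, with 9 negative members against 4, in a range of 0.0174 to 0.846), hepatocyte markers (range 0.0293 to 0.207), p53 targets (0.0116 to 0.198), cholangiocyte markers (0.0108 to 0.284), EGF family ligands (0.0108 to 0.339) and the BCL2 family (0.0104 to 0.375). The other 12 stayed between 0.0612 and 0.999. Median and mean differed in sign for RAS pathway components (0.03 and −0.08), MHC class I presentation (0.02 and −0.04), WNT targets (−0.12 and 0.82) and NRF2 targets (0.08 and −0.17).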

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

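The single genes and gene lists here drew attention because their response to RMC-7977 differed between KPCh and iAKP by the test of the difference itself. The fibroblast markers and KPCh treated library 2 were taken up for other reasons, the size of a rise in iAKP and a gap within a group. The splits of the libraries were planned, and the tests of the cholesterol genes, of KPCh treated library 2 and of the fibroblast markers were chosen only after those results were seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 5256 genes differed. In 4 of 100 splits of the libraries, the real one included, as many genes differed, and the highest of the others had 7726. All 4 were among the 10 splits that kept the real iAKP groups, and the other 90 broke up the iAKP response and gave at most 91. The share of splits therefore does not test the difference between the lines, and chance was not excluded for it. Genes changed the same way in both lines numbered 4549 in the real split, with 1 split of 100 as high and a highest other value of 1. Splits that regrouped a line left at most 1 gene called in that line, so the splits do not test whether the shared number exceeds chance. The 10 lists called for the difference were matched in 42 of 100 splits, with a highest other value of 14, so chance was not excluded for that number. For each line alone the 10 splits of its libraries are too few for a share under 0.05. The real KPCh split gave 6658 genes (1 split as high, highest other 1) and the real iAKP split 10352 (1 split as high, highest other 0). The corresponding list counts were 12 in KPCh, with 4 splits as high and a highest other of 14, and 14 in iAKP, with 1 split as high and a highest other of 12. Of the 4 KPCh splits that part all 3 replicate pairs, the real one gave 6658 genes and the highest other 0, against at most 1 among the rest.

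Cholesterol synthesis genes fell in iAKP and less or not detectably in KPCh, with a median difference of −1.94 (−1.945 before rounding). Strand-specific counting of the iAKP libraries alone was argued against as the cause, since the 14 members without an opposite-strand exon had a median difference of −1.94 (SE 0.28). Composition scaling was argued against as the whole cause by size alone. Library totals gave −1.77 over the 20 members (SE 0.23), but shifted the median difference of all genes by only 0.179. A change between these scalings could therefore not have removed the pattern. Batch stayed open and cannot be told apart from line, because 0 libraries carried the batch label of the other line. A difference between the lines themselves, which the design names, was not tested apart from batch and may account for the pattern.

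KPCh treated library 2 lay further from the untreated libraries than treated libraries 1 and 3 in cell cycle and ERK output genes (59 members). A difference by replicate number already present in the untreated libraries was argued against as the whole cause, since the untreated gap of −0.25 was 15.4% of the treated gap of −1.61. RNA of untreated cells in treated libraries 1 and 3 may contribute, and a smaller share than the needed one stayed open. The needed share was 41.1% in library 1, where 60 of 2244 fallen genes (2.7%) lay below the level it would bring, and 60.8% in library 3, where 192 did (8.6%). Mixing leaves each gene at no less than that share of its untreated level. The log2 medians of ERK output, −1.55 in library 1 and −1.83 in library 3, lay below it. The library 3 median for mitosis was −0.30. These values argue against the needed share for ERK output genes. Phlda1, Dusp4, Epha2 and Epha4 in library 1 and Epha4 in library 3 lay above it. No biological explanation was tested, because the labels name no difference between these libraries.

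Fibroblast and stellate markers rose in iAKP, with a median log2 fold change of 2.98 over 6 members, and Postn, Col1a2, Lum, Thy1, Lrat and Des of the same list failed the filter and were not tested. RNA of fibroblasts was argued against, since Postn, the highest of 4 list members under the filter, reached 0.34% of Col3a1 in any treated iAKP library, Col1a2 0.27%, Lum 0.1% and Thy1 0.07%. Composition scaling was argued against by size alone. The smallest median over 3 scalings was 2.98 (SE 1.03), while library totals shifted the median of all genes in iAKP by only 0.187. A change between these scalings could therefore not have removed the rise. Treatment, the design's own explanation, remains as a hypothesis, found and examined on the same libraries. Of the 6 measured markers, Pdgfra and Pdgfrb also stand in the receptor tyrosine kinase list.

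Single genes with the largest differences, on the log2 scale, were Grem1 (6.94), Adamts5 (6.46), Galnt18 (5.90), Aqp8 (5.78), Sulf2 (5.77) and Spata20 (5.34) on the positive side. On the negative side stood Sox8 (−6.70), Scin (−6.45), Nckap1l (−6.11), Gdf15 (−5.99), Tecta (−5.82) and Apoa1 (−5.68). For Adamts5, Aqp8, Spata20, Sox8, Nckap1l and Tecta a group held at most 3 counts, so the fitted value depends on the prior count and is no measure of the fold. Without KPCh treated library 1 the edgeR adjusted p was 0.909 for Nckap1l and 0.897 for Tecta, the highest in ranges that began at 5.4e-05 and 0.000156.

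Beside cholesterol synthesis, 9 lists differed, with these median differences. Mitosis was at −1.33, cytokines and immune ligands at −1.27, the integrated stress response at −0.76, the NOTCH pathway at −0.74, and CDK inhibitors and quiescence at −0.24. Mesenchymal genes were at 0.66, YAP/TEAD targets at 0.52, glycolysis at 0.45, and receptor tyrosine kinases and adaptors at 0.40. None of the 10 lists kept its camera call with an estimated correlation.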

How the results depend on the processing

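The restriction to genes without an opposite-strand exon overlap was chosen after the file headers were read, and all other alternatives were planned. No result reversed. Of 15 counts of genes or lists, 289 of 311 alternative values stayed within 1.5 times the reported count and 22 moved. Of 270 results for named genes, 236 kept their side of the threshold under all alternatives, and of 5538 values 130 lost and 6 gained the call. Of 90 list tests 40 kept theirs, with 69 of 1853 values losing and 58 gaining the call, and 419 of 3720 member counts moved. With library totals 1701 genes were negative for the difference, and with a mean of at least 5 CPM 2 lists were positive; the causes were not tested. With each line fitted alone, KPCh had 2158 genes higher and 2017 lower, 1411 genes were higher in both lines and 277 changed in opposite directions, on the larger spread of KPCh. With an estimated correlation 0 lists were higher and 2 lower in KPCh, 1 and 1 in iAKP, and 0 and 0 in the difference. Among genes without an opposite-strand exon, 2229 were higher in KPCh, 3340 lower in iAKP, 1540 negative in the difference and 1420 higher in both, with fewer genes tested. There 2 KPCh lists were higher and 10 lists negative in the difference, and the cause was not tested.

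Leaving out each library in turn gave 2721 to 3891 higher and 2789 to 3437 lower genes in KPCh, 4767 to 5780 and 4474 to 5327 in iAKP, and 2038 to 3336 positive and 1738 to 2863 negative in the difference. The lowest negative counts came without iAKP untreated library 1 (1738) or 3 (1785). Lists positive in the difference numbered 2 to 4, with 2 without KPCh treated library 1 or 2. With the replicate number as a block, KPCh had 3928 higher and 3634 lower genes, iAKP 5429 and 5365, and the difference 2876 and 3264. The block changed the KPCh calls of YAP/TEAD targets and MHC class I presentation, the counts given beside the KPCh and difference lists, and the difference calls of the receptor, NOTCH and CDK inhibitor lists. It also raised member counts of the difference from 3 to 5 negative RAS pathway components, 2 to 5 positive lysosome genes, 1 to 3 negative MHC class I genes and 2 to 5 positive NRF2 targets. Among the 270 results run singly the KPCh calls of Trib3 and Gsta4 were lost and a difference for Trp53 was gained, and no other of them changed. Genes named only as list members, such as Dusp1 and Zfp36, had no single result under the block. In iAKP same-numbered libraries correlated at 0.014, −0.018 and −0.022 and were not taken as pairs, and not every library correlated best with its own number. Under the block the iAKP interferon call was lost and those of the cytokine and hepatocyte lists were gained. Across genes the correlation of both responses was 0.221 without a filter and 0.592 at a mean of at least 5 CPM, and depth limits genes near the floor. Camera was not run for DESeq2, and the difference was not fitted with each line alone.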

Other observations

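The test of Kras copies over genes above the floor was chosen only after the result was seen, and genes named here outside the naming rule were chosen after their values were seen. A few genes of the naming rule are known from immune cells. The fixed list of immune cell markers had no call in either line. That test bears on the response to treatment, not on whether such cells were present. Of that list, Adgre1, Lyz2, Cd3e, Itgam, Tyrobp and Cd79a failed the filter, at no more than 0.27 CPM by library totals in any library. Mrc1 stood at 116.6 CPM in untreated KPCh and 349 CPM in untreated iAKP, Il5ra at 498.5 and 63.4 CPM, and Lilr4b at 56.7 CPM in iAKP. Ptprc, the pan-leukocyte gene, stood at 0.714 and 0.253 CPM. Lcn2, C3 and Saa3, genes of the acute phase response, rose in iAKP from 34.5 to 159.3 CPM, from 70.2 to 541 CPM and from 7.14 to 509 CPM.

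In untreated cells 4 genes picked for their values are given for both lines, with no test of a list, and line cannot be told apart there from batch label and counting. The cadherin gene Cdh1 stood at 842 ± 212.7 CPM in KPCh and 11.2 ± 1.04 CPM in iAKP (SD, n = 3), the keratin gene Krt7 at 1617 ± 283.6 and 17.0 ± 2.3 CPM, and Epcam at 622 ± 122.9 and 76.9 ± 3.03 CPM. The transferrin gene Trf stood at 31.4 ± 8.52 and 6798 ± 350.7 CPM.

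Kras counts were 15.6 times higher in untreated iAKP than in untreated KPCh (log2 ratio 3.96, with 0.1 CPM added to each mean), and the hypothesis was tested that iAKP carries extra copies of the chromosome 6 segment around Kras. The prediction was a raised median over the protein-coding genes within 1 Mb, at least 1.98. The 11 such genes had a median log2 ratio of 4.31 (SE 1.77), but that value belongs to Tuba3b, which had no counts in untreated KPCh, and Lrmp and Lmntd1 were also under the floor there, as Sspn was in untreated iAKP. Of 12949 runs of 11 neighbouring genes 4 (0.0309%) had a median as high, the 99th percentile being 1.34. The runs took in Kras and its neighbours, and the run from Sox5 through Kras to Sspn was among the 4. The 4 are therefore not all other places in the genome. Their small share goes with the hypothesis but rests on the same values. Over the 7 genes above the floor in both lines the median was 1.65 (SE 1.39), under the level predicted and not under 1, so the hypothesis stayed open. Bcat1 stood at 29.6 CPM in KPCh and 1238 CPM in iAKP (5.38) and Etfrf1 at 11.2 and 372 CPM (5.04). Rassf8 (0.20), Bhlhe41 (0.00) and Itpr2 (−0.43) lay near or under 0. Position was looked at after the values were seen. Sox5, Bcat1, Lrmp, Casc1, Etfrf1, Lmntd1 and Tuba3b, from 143774151 to 145567205, had log2 ratios of 1.65 to 9.74. Rassf8, Bhlhe41, Sspn and Itpr2, from 145692474 on, had 0.20 or lower. The raised genes thus formed a run that holds Kras, and the median over the 7 genes mixed both sides of its edge. Extra copies may account for part of the Kras level, but DNA was not analysed here, and a difference in regulation of the region, in batch or in counting between the lines also stays open.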
